A study of Mus musculus with 6 samples.

How the data were processed

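RNA sequencing of 6 samples labelled primary mouse vascular smooth muscle cells was used, 3 knocked out for Nono (KO) and 3 wild type (WT). Per the labels' protocols, the cells grew in medium with serum without further treatment, total RNA was isolated with column kits and libraries followed standard Illumina protocols. Groups and replicate numbers were taken from the sample titles. The deposited table holds raw read counts and FPKM per Ensembl gene for each sample, per the file headers. Per the submitters' processing notes, CASAVA 1.8, HISAT2, SAMtools 1.3.1 and edgeR were used with the mouse build GRCm39. The notes name no role for each tool, and the read counter, its strand setting and the annotation release are not given in the sources used here, so reads of a gene and of an overlapping or antisense gene may not be separable. The deposited FPKM values were normalized by the authors and are not the counts rescaled by a gene length and a library factor: between pairs of samples, the ratio of FPKM to count lay over 0.1 on the log2 scale from its median change in 17.1% to 27.3% of the 7633 genes with at least 100 counts and an FPKM of 5 in every sample. They entered only an alternative test.

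The table lists 56393 genes, of which 55394 (98.23%) were matched by Ensembl ID to a symbol in GENCODE M21. That annotation is of build GRCm38, so it served only for symbols, chromosomes, gene order, biotypes and transcript GC content, and no coordinates are given. Library totals ranged from 56529170 to 61670083 counts. The floor for a gene at 0 in a group was set at 3 counts over the group, which is 0.0161 CPM in WT and 0.0174 CPM in KO. Floors cover counting error only, because PCR duplicates are not independent molecules. Replicates of a group differed by more than sampling noise (chi-square per degree of freedom 22.6 to 34.8), so each counted as 1 sample.

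Genes were filtered with filterByExpr by group, which kept 18732, scaled with TMM factors (1.04 to 1.06 in WT, 0.952 to 0.96 in KO) and tested with the robust quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, KO against WT over all 6 samples without covariates, with Benjamini-Hochberg adjustment at 0.05. CPM are TMM-scaled, with mean ± SD over 3 libraries. Gene lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the 36 lists, each with at least 5 tested members. Alternatives were camera with an estimated correlation, fry, the size factors and the Wald test of DESeq2 1.42.0, limma-voom, other filters and thresholds, the replicate number as a block, and leaving out each library. Added after the data had been seen were scaling by total counts, autosomal genes only, and limma on log2(FPKM + 0.1). Camera with an estimated correlation takes its p-value on the residual degrees of freedom of 6 libraries. A list can therefore lose its call there whatever its correlation.

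The design, the lists, most alternatives and the rule for naming genes were fixed before the data were examined. The rule named Nono, Bmp2, the 10 genes with the largest increase and the 10 with the largest decrease (adjusted p under 0.05, at least 5 CPM in the higher group, no overlap of the groups, and no predicted, RIKEN, pseudogene or unnamed locus), the 4 members of each list with the smallest adjusted p where they passed and otherwise up to 2, and a fixed set of smooth muscle, bone and paraspeckle genes. Some members were left out for brevity, and the result of 1 list member is not reported here. Grem1, Col3a1, Col1a1, Atf4, Trib3, Ddx3y, Xist, Id3, Bmp5, Mmp2, Mcm2 and Cdkn2a lie outside the rule and were chosen after their values were seen. The imprinted and Hox gene lists of the closing section were drawn up after the first results, those of Meg3, Dlk1, Sgce and the fibroblast marker Dcn among them, had been seen, and before the results of these lists were computed. Imprinted genes were assigned to loci by hand.

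The test was checked on simulated counts for 18732 genes, drawn from the WT means and the library sizes of the KO against WT comparison. It recovered 36% of genes changed 1.5-fold, 80% at 2-fold, 94% at 4-fold and 98% at 8-fold, with 17 false calls (9.04% of the calls). Only 50 genes expressed in WT were changed at each fold, and a list of 30 at 1.5-fold. In the data 69.29% of tested genes passed, some of them at 0 in 1 group, so these rates need not hold there.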

Results

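Gene expression was measured by RNA sequencing in cells labelled primary mouse vascular smooth muscle cells, the contractile cells of the vessel wall. They were either knocked out for Nono (KO, n = 3 libraries) or wild type (WT, n = 3 libraries). Nono encodes an RNA- and DNA-binding protein of paraspeckles, nuclear bodies built on the long noncoding RNA Neat1. The series is about vascular calcification and transcription of the gene for bone morphogenetic protein 2 (BMP2). The question behind the comparison is which genes differ between KO and WT cells, Bmp2 among them, in cells that received no further treatment. Total counts per library were 60864603, 56529170 and 60542677 in WT and 61662507, 57295800 and 61670083 in KO. Between 23080 and 23400 genes had at least 1 count in a library. The log2 CPM of libraries of the same genotype correlated across genes at 0.979 to 0.983, and that of libraries of different genotype at 0.804 to 0.809, where genes are not independent replicates. The labels do not say whether the replicates were separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.

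Nono was lower in every KO library. The gene lies on chromosome X and its level was 514.9 ± 10.996 CPM (SD, n = 3) in WT and 54.0 ± 2.55 CPM (SD, n = 3) in KO, a 9.54-fold difference (log2 fold change -3.25 ± 0.05 SE, edgeR quasi-likelihood test, adjusted p = 1.63e-09). Nono transcript was still counted in every KO library (51.1 to 55.97 CPM). Of 30 tested paraspeckle genes, 9 were higher and 14 lower in KO, or 15 lower when adjusted over the list alone, and the list did not pass the camera set test (adjusted p = 0.209). The list includes Nono itself, which is counted among the lower genes. With scaling by total counts 4 were higher and 19 lower, and from the deposited FPKM 4 and 15. Neat1 rose from 423 ± 35.4 to 1733 ± 39.4 CPM. Srsf10, a splicing factor, fell from 218 to 75.8 CPM and Taf15, a FET-family RNA-binding protein, from 217 to 104 CPM. Pspc1, a partner of Nono in the same protein family, fell by 0.78 ± 0.15 (SE) on the log2 scale (edgeR adjusted p = 0.00225). Sfpq, the third member of that family, was at 319 ± 26.2 CPM in WT and 307.7 ± 9.98 CPM in KO and did not pass the test (edgeR adjusted p = 0.485), although it was called lower in 3 alternatives. Of 25 tested neighbours of Nono on X, 10 were higher and 8 lower (camera adjusted p = 0.967), with a median log2 fold change of -0.06 and a mean of 0.50, or 0.13 without Chic1. Chic1 was at 19.97 ± 0.97 CPM in KO. In WT it was counted in replicate 1 alone (0.0792 CPM), with a log2 fold change of 9.43 (690-fold). Without that library the bound, against a floor of 3 counts over the other WT libraries, was 818-fold. This bound leaves out the WT counts and is not a minimum over all libraries. With scaling by total counts 9 were higher and 9 lower. Igbp1 was 2.68-fold higher and Kif4, a mitotic kinesin, 2.67-fold lower.

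**Figure D1:**
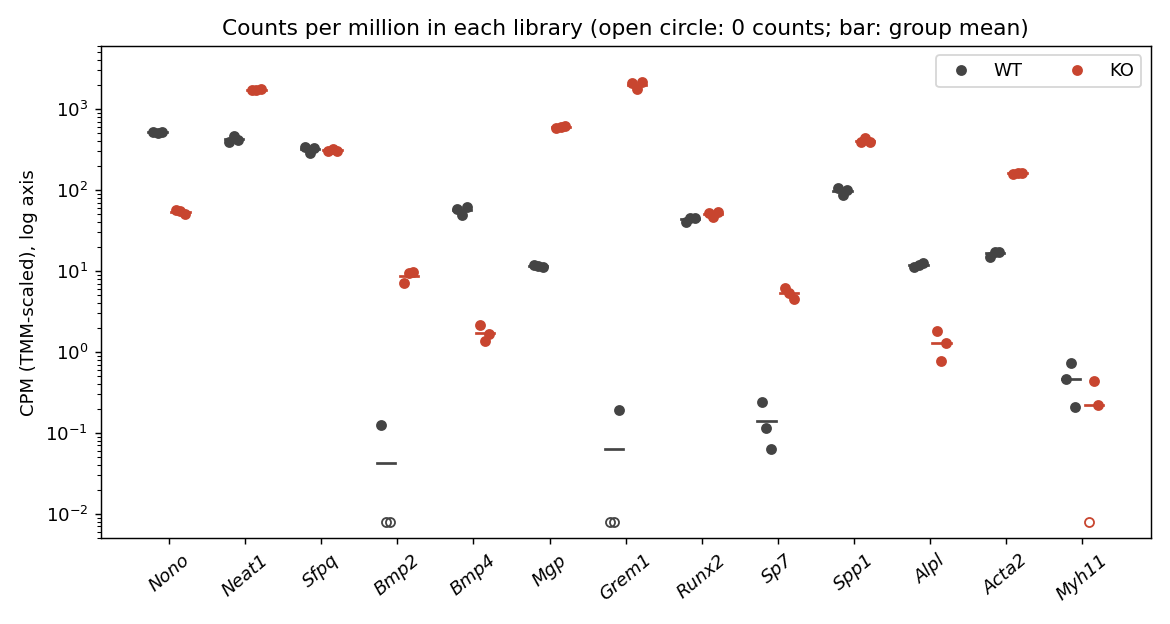
CPM (log axis) of 13 genes in each of the 3 WT and 3 KO libraries, with bars at the group means and open circles, drawn at the bottom of the axis, for libraries with 0 counts. Nono lies near 514.9 CPM in WT and 54.0 CPM in KO, Bmp2 was counted in 1 WT library and in all KO libraries, and the Sfpq values of the groups overlap.

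Bmp2 was higher in KO. It had 8 counts in the WT libraries together, all of them in WT replicate 1, and 1509 counts in the KO libraries, or 0.0423 ± 0.0732 CPM in WT against 8.76 ± 1.43 CPM in KO (SD, n = 3 each; log2 fold change 7.60 ± 0.72 SE, edgeR adjusted p = 4.95e-05). Without WT replicate 1 the WT libraries were at 0 counts. Against a floor of 3 counts over them (0.0244 CPM), the difference was then at least 359-fold. That bound leaves out the WT counts of Bmp2, exceeds the 195-fold fit over all libraries and is not a minimum over them. Of 22 tested BMP ligands and receptors, 14 were higher and 5 lower, or 6 lower when adjusted over the list alone (camera adjusted p = 0.116, and 0.0478 without a filter on low counts). Bmp4, a closely related ligand, went the other way, from 56.7 ± 6.62 CPM in WT to 1.73 ± 0.41 CPM in KO, and Bmp5 from 9.16 CPM to 0 counts. Gdf10 was at 0 counts in WT and at 48.5 ± 0.81 CPM in KO. Bmp1, a protease that cuts procollagen rather than a ligand, was 3.96-fold higher. Of 14 BMP antagonists and extracellular BMP-binding genes, 11 rose and 3 fell (camera adjusted p = 0.0113, and adjusted p = 0.209 with an estimated correlation). Mgp rose from 11.4 ± 0.30 to 596 ± 22.7 CPM, Bmper 8.73-fold and Htra3 11.7-fold. Grem1, a secreted BMP antagonist, was at 1991 ± 189 CPM in KO and was counted in WT in replicate 3 alone (0.191 CPM), with a log2 fold change of 14.87. Without that library the difference was at least 81695-fold against a floor of 3 counts over the other WT libraries. This bound too leaves out the WT counts and is not a minimum over all libraries. Of 18 BMP target genes, 5 were higher and 8 lower (camera adjusted p = 0.546). Id1, a direct target of BMP signalling, fell from 101 to 53.2 CPM, Smad9 4.99-fold and Hes1 11.5-fold, while Sp7, an osteoblast transcription factor also on this list, rose from 0.139 to 5.33 CPM, a 37.6-fold difference. Id3, also a direct target, was at 182 CPM in WT and 187 CPM in KO (edgeR adjusted p = 0.534), and the sign of that difference turned in 3 alternatives.

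The KO and WT libraries differed over much of the transcriptome. Of 18732 tested genes, 12980 (69.29%) passed an adjusted p of 0.05, 6578 higher and 6402 lower in KO (edgeR), and 7757 of these differed at least 2-fold. In 14139 genes (75.48%) the 3 values of each group did not overlap, where chance gives 10%. With scaling by total counts the median log2 fold change of the tested genes moved from 0.0313 to -0.0992 and the share of changed genes that were higher from 50.7% to 45.4%. Genes were ranked by fitted log2 fold change, which rests on the fit where a group is at 0, as only a bound is measured there. Under the naming rule, the genes with the largest increases had 0 counts in all WT libraries. They were Gas1, a membrane protein linked to growth arrest (837 ± 17.5 CPM in KO, at least 51879.9-fold against a floor of 3 counts over the group), the imprinted noncoding RNA Meg3 (803 CPM), the scavenger receptor Colec12 (670 CPM), the Wnt antagonist Sfrp1 (660 CPM), Mark1 (206 CPM), Csmd1 (193 CPM), S1pr3 (132 CPM), the imprinted gene Dlk1 (130 CPM), the homeobox gene Irx1 (102 CPM) and Itgbl1 (97.3 CPM). Those with the largest decreases had 0 counts in all KO libraries. Gpr141 (96.6 ± 13.2 CPM in WT) was at least 5554-fold lower, followed by Tspan8 (73.0 CPM), Tnfsf15 (51.4 CPM), Pcolce2 (45.3 CPM), Trpc1 (35.2 CPM), Cacng4 (27.7 CPM), the cardiac homeobox gene Nkx2-5 (17.9 CPM), Xlr3c (14.01 CPM), Inpp5j (13.6 CPM) and Grhl1 (12.5 CPM). In all, 100 genes were at 0 in WT and at 5 CPM or more in KO, and 28 were at 0 in KO and at 5 CPM or more in WT. Floors cover counting error only.

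**Figure D2:**
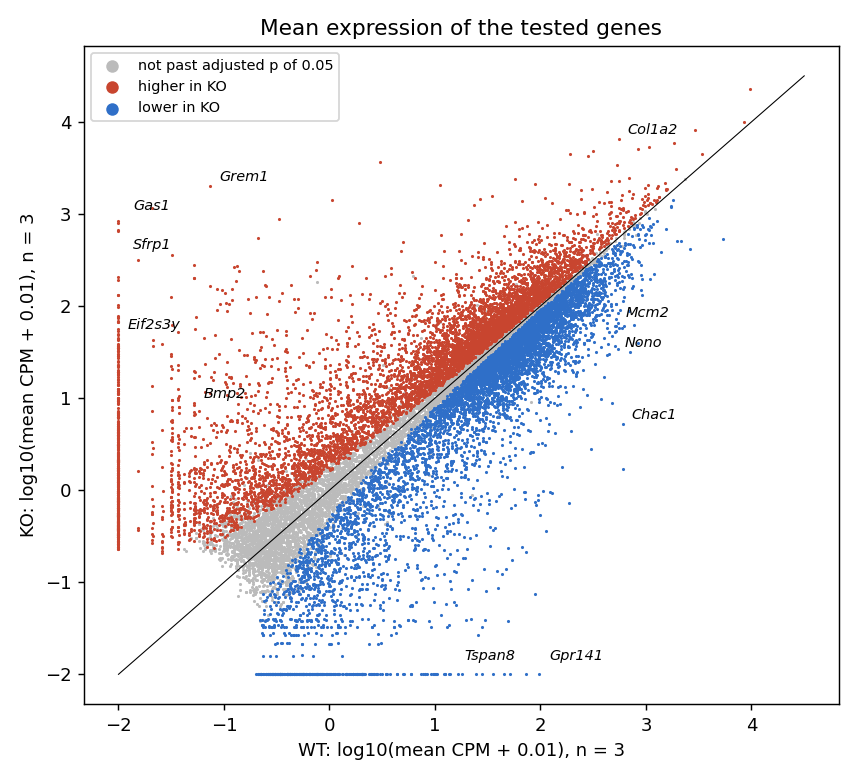
Mean expression of the 18732 tested genes in WT (x axis) and KO (y axis), each as log10 of the mean CPM plus 0.01 over 3 libraries, with genes higher in KO in red, lower in blue, the rest in grey, and a line of equal expression. The columns of points at the left and bottom edges are genes with 0 counts in all libraries of WT or KO.

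Transcripts of the Y chromosome were counted in KO. Eif2s3y, Kdm5d and Uty were at 49.5 ± 3.19, 38.2 ± 1.38 and 18.1 ± 0.82 CPM in KO and at 0 counts in all WT libraries. Ddx3y was at 52.5 CPM in KO and in WT was counted in replicate 3 alone (0.0795 CPM), with a log2 fold change of 10.82. Without that library it was at least 2155-fold higher against a floor of 3 counts over the other WT libraries. That bound leaves out the WT counts and exceeds the 1814-fold fit over all libraries. The 4 genes together reached 149.9 to 163.3 CPM in the KO libraries and 0 to 0.0795 CPM in the WT libraries. Xist, the noncoding RNA of the inactive X chromosome, was between 0.267 and 0.682 CPM in all 6 libraries and did not pass the test (edgeR adjusted p = 0.884). Eif2s3x, the X-linked partner of Eif2s3y, was 1.94-fold lower. Of 9 tested sex-linked genes 6 were higher and 1 lower (camera adjusted p = 0.0271, and adjusted p = 0.209 with an estimated correlation), or 5 and 2 from the deposited FPKM. This difference separated the same libraries as genotype and is shared by every comparison described here.

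Smooth muscle genes went in both directions. Of 26 tested contractile genes, 14 were higher and 7 lower in KO (camera adjusted p = 0.138). Acta2, smooth muscle actin, rose from 16.4 ± 1.27 to 161 ± 2.40 CPM, Flna 2.41-fold, Tgfb1i1 4.23-fold and Ppp1r12b 6.01-fold. Tagln rose from 0.859 to 15.01 CPM. Cnn1 was at 3.49 CPM in KO and in WT was counted in replicate 3 alone, with a log2 fold change of 7.21, or at least 143-fold higher without that library against a floor of 3 counts over the others. Myh11, the smooth muscle myosin heavy chain, was at 0.467 CPM in WT and 0.219 CPM in KO. It did not pass the test (edgeR adjusted p = 0.375). In WT, Myh11, Tagln and Cnn1 thus lay under 1 CPM, and the identity of the cells rests on the labels. Of 21 genes linked to the synthetic, proliferative state, 16 rose and 5 fell (camera adjusted p = 0.0271, and adjusted p = 0.209 with an estimated correlation). Pdgfrb rose from 116 to 757 CPM, Mmp3 from 0.648 to 211 CPM and Mmp2 from 11.2 to 2084 CPM. Klf4, a transcription factor of this state, fell from 524 to 106 CPM and Ereg, an epidermal growth factor receptor ligand, from 132 to 15.5 CPM. The Y-linked sum was 149.9 to 163.3 CPM in the KO libraries of these comparisons.

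Genes of bone formation and of mineral control also differed. Of 26 osteogenic and chondrogenic genes, 16 were higher, or 17 when adjusted over the list alone, and 7 lower (camera adjusted p = 0.107). Spp1, osteopontin, rose from 97.3 ± 9.29 to 407 ± 23.6 CPM, Sox9, the chondrocyte transcription factor, from 39.1 to 106 CPM and Col11a1 from 7.14 to 35.7 CPM. Sp7, also called osterix and shared with the BMP targets, had a log2 fold change of 5.23, or 5.87 without WT replicate 1. Msx2 was at 0 counts in WT and 2.19 CPM in KO, at least 136-fold higher. Runx2 was at 43.4 ± 2.98 CPM in WT and 50.2 ± 3.86 CPM in KO (log2 fold change 0.21 ± 0.08 SE, edgeR adjusted p = 0.0492), and this call was lost in 7 of 14 alternatives. Alpl, the phosphatase that breaks down the mineralization inhibitor pyrophosphate, fell from 11.9 ± 0.66 to 1.29 ± 0.51 CPM. Of 22 mineralization inhibitors and phosphate-handling genes, 14 rose and 4 fell, or 15 and 5 when adjusted over the list alone (camera adjusted p = 0.0288, and adjusted p = 0.209 with an estimated correlation). Besides Mgp and Spp1, which this list shares with others, Gas6 rose 15.1-fold and Fgfr1 4.60-fold. The KO libraries again were those with Y-linked transcripts (149.9 to 163.3 CPM).

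Extracellular matrix genes were higher in KO. Of 42 collagen and elastic fibre genes, 36 rose and 4 fell (camera adjusted p = 1.77e-08, and adjusted p = 0.209 with an estimated correlation). Col1a2 rose from 552 ± 24.8 to 6442 ± 235 CPM, Col1a1 6.07-fold, Col5a2 6.36-fold, Sparc 11.6-fold and Postn 175-fold. Col3a1 rose from 3.03 to 3712 CPM. Of 30 matrix proteases and their inhibitors, 22 rose and 6 fell (camera adjusted p = 0.000155, and adjusted p = 0.209 with an estimated correlation). Mmp14, a membrane-bound collagenase, rose from 95.4 to 815 CPM and Adamts5, an aggrecanase, from 16.9 to 399 CPM. Adamts1 rose 8.80-fold and Adamts2, a procollagen-processing enzyme, 11.4-fold. Of 22 genes of TGF-beta signalling, 15 rose and 3 fell (camera adjusted p = 0.00638, and adjusted p = 0.209 with an estimated correlation), or 14 and 5 both with scaling by total counts and from the deposited FPKM. Tgfbi rose from 1.89 to 793 CPM, Ltbp2 from 1.04 to 1432 CPM, Tgfbr2 6.64-fold and Tgfbr3 4.61-fold.

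Some markers of other cell types differed between KO and WT, in the same libraries that carried Y-linked transcripts. Of the lists below only fibroblast markers passed camera with its preset correlation, and 69.29% of all tested genes passed the gene test. Members removed by the low-count filter are not counted. Tested were 17 of 18 listed fibroblast, 8 of 12 pericyte, 9 of 18 endothelial and 7 of 14 mesothelial and epithelial markers. Of macrophage and leukocyte markers 7 of 20 were tested, and of adipocyte markers 6 of 14. For Schwann and neural markers it was 8 of 15, and for skeletal and cardiac muscle markers 9 of 24. Of 17 fibroblast markers, 14 rose and 2 fell (camera adjusted p = 0.000507, and adjusted p = 0.209 with an estimated correlation). Dcn, decorin, rose from 26.5 ± 3.92 to 1464 ± 53.8 CPM, Serpinf1 22.6-fold, Ackr3 6.18-fold and Gsn 3.55-fold. Of 8 pericyte markers, 5 were higher and 2 lower (camera adjusted p = 0.191), with Rgs5 19.4-fold higher and Mcam 21.3-fold lower. Of 9 endothelial markers, 3 were higher and 5 lower (camera adjusted p = 0.436), with Eng at 2.42 CPM in WT and 134 CPM in KO and Flt1 4.83-fold lower. Of 7 mesothelial and epithelial markers, 2 were higher and 4 lower (camera adjusted p = 0.453), and the keratin gene Krt19 fell 7.07-fold. Wt1, a mesothelial transcription factor, rose from 0.0545 to 2.03 CPM, with a log2 fold change of 5.18, or 5.91 without WT replicate 2. Of 7 macrophage and leukocyte markers, 3 were higher and 2 lower (camera adjusted p = 0.595). Cd14 was 6.02-fold higher and Cd74, the MHC class II invariant chain, 23.8-fold lower. Of 6 adipocyte markers, 4 were higher and 2 lower (camera adjusted p = 0.669), with lipoprotein lipase, Lpl, falling from 339 to 31.8 CPM and Plin4 rising 15.1-fold. Of 8 Schwann and neural markers, 4 were higher and 1 lower (camera adjusted p = 0.595), with Mbp 5.92-fold lower and Tubb3 2.03-fold higher. Of 9 skeletal and cardiac muscle markers, 2 were higher and 4 lower (camera adjusted p = 0.324), or 1 and 4 under the replicate block, with Tnnt2 7.20-fold lower.

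Genes of DNA replication and division were lower in KO. All 35 tested S phase genes fell (camera adjusted p = 1.01e-12, and adjusted p = 0.309 with an estimated correlation). The helicase subunit Mcm2 fell from 525 ± 19.96 to 60.6 ± 6.998 CPM, the replication licensing factor Cdt1 8.599-fold, the polymerase subunit Pola1 8.49-fold, the primase subunit Prim1 6.66-fold and Dtl 8.45-fold. Of 40 genes of G2 and mitosis, 31 fell and 4 rose (camera adjusted p = 0.000118, and adjusted p = 0.414 with an estimated correlation), or 31 and 2 from the deposited FPKM. Top2a fell from 925 ± 8.97 to 195 ± 11.8 CPM, Birc5 4.23-fold, Kif20b 3.59-fold and Tpx2 2.53-fold. Of 26 senescence genes and p53 targets, 15 were higher and 8 lower (camera adjusted p = 0.141). The cell cycle inhibitor Cdkn1a rose from 51.9 to 364 CPM, Ccng1 9.996-fold and Phlda3 2.79-fold, while Sesn2 fell 3.01-fold. Cdkn2a, another cell cycle inhibitor, fell from 164 to 113 CPM. Of 45 listed replication-dependent histone genes, only 15 were matched by symbol and 8 tested, so most of the list was not measured. Of these 8, 2 were higher and 0 lower (camera adjusted p = 0.302), Hist1h2bc 15.5-fold and Hist1h1c 8.17-fold. The Y-linked sum separated these libraries in the same way.

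The counts of genes higher and lower in KO differed between the stress and immune lists, which were not tested against each other. Of 34 genes of the unfolded protein and amino-acid stress responses, 27 fell and 7 rose (camera adjusted p = 0.000122, and adjusted p = 0.309 with an estimated correlation), or 27 and 3 both with scaling by total counts and from the deposited FPKM. Chac1, a glutathione-degrading enzyme, fell from 600.4 ± 15.9 to 5.19 ± 0.47 CPM, the cystine transporter Slc7a11 from 372 to 9.77 CPM, Psat1, of serine synthesis, from 619 to 60.1 CPM and the mitochondrial folate enzyme Mthfd2 from 331 to 23.6 CPM. The transcription factor Atf4, which drives many of these genes, fell 2.97-fold and its target Trib3 23.5-fold. Of 34 inflammatory cytokines and NF-kB targets, 23 rose and 7 fell (camera adjusted p = 0.00265, and adjusted p = 0.209 with an estimated correlation). The chemokine Cxcl12 rose from 316 to 4873 CPM, the acute-phase gene Saa3 44.6-fold and Ccl2 9.67-fold, while Nfkb2 fell 2.99-fold. Of 38 interferon response genes, 12 were higher and 20 lower (camera adjusted p = 0.116, and 0.0469 without a filter on low counts). Rsad2 fell from 255 to 12.5 CPM, Oasl1 from 107 to 0.964 CPM, Cxcl10 9.76-fold and Cgas, the cytosolic DNA sensor, 6.25-fold.

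All 13 mitochondrially encoded genes were higher (camera adjusted p = 0.00265, and adjusted p = 0.444 with an estimated correlation), 11 with scaling by total counts and 9 from the deposited FPKM, with mt-Nd2 rising 2.24-fold and mt-Nd1 1.98-fold. Mitochondrial transcripts made up 1.98% to 2.07% of counts in WT and 2.29% to 2.44% in KO. Of 45 nuclear genes of oxidative phosphorylation, 11 were higher and 20 lower (camera adjusted p = 0.125). With scaling by total counts 6 were higher and 28 lower and the list passed (adjusted p = 0.0337), and from FPKM 7 were higher and 30 lower. Cycs, cytochrome c, fell 6.45-fold, Uqcrq 3.48-fold and Cox6a1 2.48-fold. Of 60 cytosolic ribosomal protein genes, 41 rose, or 42 when adjusted over the list alone, and 12 fell (camera adjusted p = 0.00564, and adjusted p = 0.704 with an estimated correlation). Rpl34 was 16.9-fold and Rpl3 2.68-fold higher, values that are uncertain where such genes share reads with processed copies, which was not tested. Of 34 hypoxia and glycolysis genes, 19 rose and 7 fell (camera adjusted p = 0.0322, and adjusted p = 0.439 with an estimated correlation), a list call lost with scaling by total counts (adjusted p = 0.0579). Adm was at 0 counts in WT and 34.9 CPM in KO, Egln3 was 19.2-fold higher, Aldoa 2.43-fold higher and Car12 47.0-fold lower. Of 29 genes of cholesterol synthesis, 12 were higher and 9 lower (camera adjusted p = 0.595), with Insig1, a regulator of sterol sensing, 10.2-fold higher and Scd1, a fatty acid desaturase, 1.82-fold lower.

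Signalling and clock genes completed the lists. Of 38 Wnt signalling genes, 25 rose and 10 fell (camera adjusted p = 0.0146, and adjusted p = 0.209 with an estimated correlation), a list call lost under a filter of 1 CPM in 3 libraries (adjusted p = 0.0746). Ccn5 rose from 3.79 to 223 CPM, and the receptors Fzd8 and Fzd2 30.3-fold and 4.60-fold. Of 16 Notch genes, 6 were higher and 6 lower (camera adjusted p = 0.595), with the ligand Jag1 2.78-fold lower and Maml2 2.30-fold higher. Of 21 circadian clock genes, 8 were higher and 11 lower (camera adjusted p = 0.546), with Cry1 6.38-fold lower and Bhlhe40 4.73-fold higher. Of the 36 lists, 16 passed camera with its preset correlation and 0 with an estimated correlation. Lists estimated below the preset 0.01, such as BMP antagonists (-0.0601) and the synthetic state (-0.00117), lost their call as well. The estimated setting has few degrees of freedom with 6 libraries, so these losses need not come from correlated genes. Counts adjusted over the list alone are given where they differed from those over all genes tested.

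**Figure D3:**
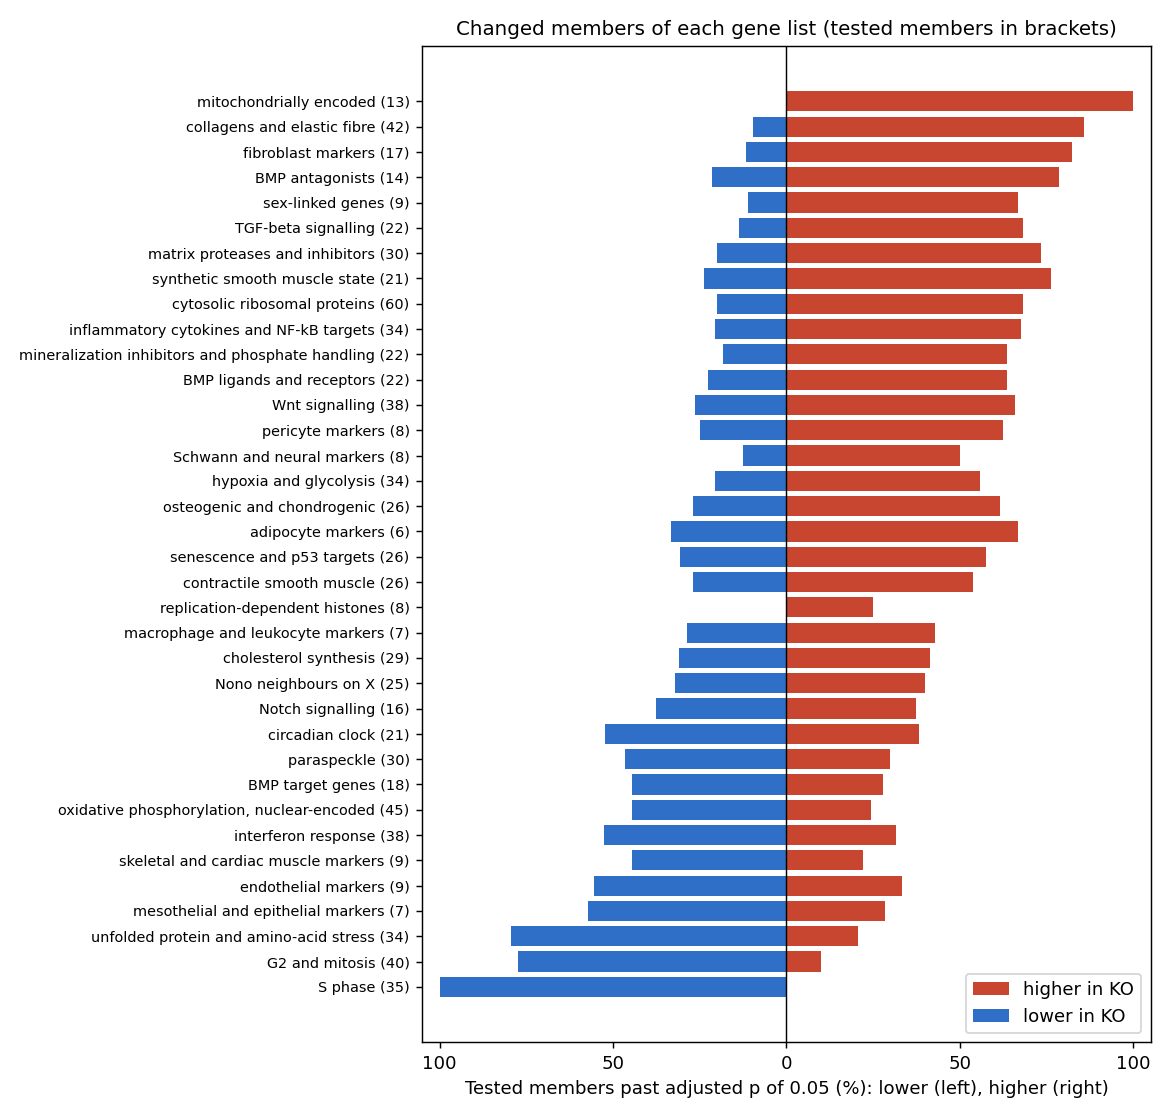
Share of the tested members of each of the 36 gene lists that were higher (red, right) or lower (blue, left) in KO at an edgeR adjusted p of 0.05, in percent, with the number of tested members in brackets. All 35 S phase genes lie on the lower side and 36 of 42 collagen and elastic fibre genes on the higher side.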

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

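Scaling by total counts, autosomal genes only and the FPKM test were chosen after the data had been seen, and the other alternatives before. The number of changed genes lay between 11026 and 13368 over the scalings, filters, tests and the stricter adjusted p, was 12364 to 12765 with 1 library left out, and fell to 7757 when at least a 2-fold change was also required, by construction. Nono stayed lower in every alternative (-3.282 to -3.215 with 1 library left out) and Bmp2 higher (7.04 to 12.02 with 1 library left out, the highest a fitted value without WT replicate 1, the WT library that held its counts, and 4.287 from FPKM). Gene lists past camera numbered 16 of 36 in the preset test, 16 to 16 with 1 library left out, 18 with no filter, 15 with the filter of 1 CPM, 0 with an estimated correlation and 33 with fry, which asks whether a list moves at all rather than whether it moves more than other genes. Under the replicate block 12233 genes changed and Runx2 was lost (adjusted p = 0.0871, range over its alternatives in which it was lost 0.066 to 0.43). Samples with the same number did not deviate together (correlations -0.024, 0.018 and -0.009), so the numbers were not treated as pairs. Over 177 genes (those of the rule and the 12 added) and 14 alternatives, 4 values could not be had (Myh11, Myh6, Tnni1 and Xist under the filter of 1 CPM), 2456 gene values kept direction and call, 7 became weaker (all Runx2), 3 stronger (all Sfpq) and 8 reversed. The reversals had small log2 values: With 1 library left out, Sfpq ranged from -0.1166 to 0.001511 (positive without WT replicate 1), Xist from -0.2225 to 0.3255 (negative without WT replicate 2, and -0.1104 without KO replicate 1) and Id3 from -0.001871 (without WT replicate 1) to 0.08629. Xist was -0.04012 with total counts and -0.002655 from FPKM, and Id3 -0.08602 and -0.05508. Among lists, the neighbours of Nono on X changed direction with no filter (adjusted p = 0.992), under the replicate block (0.966), without KO replicate 3 (0.901; 0.87 to 0.946 over the left-out libraries) and with total counts (0.982). With fry the direction turned for BMP targets (0.00956), adipocyte markers (2.08e-06) and Schwann and neural markers (0.987). The cause was not tested for any of these. Depth limits genes near the floor: Myh11, Xist and the WT levels of Bmp2 and Grem1 rest on few counts.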

Other observations

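Of the tests below, those on Hox genes, imprinted genes as a class, chromosomes, neighbouring genes and GC content were written before their results were seen, although Meg3, Dlk1, Sgce and Dcn had been seen and the chromosome shifts were known before the GC test; all others, that per imprinted locus included, were chosen after the result was seen. Imprinted genes, expressed from the allele of 1 parent, differed at least 4-fold more often than genes matched on expression. Of 30 tested imprinted genes other than Meg3, Dlk1 and Sgce, 17 (56.7%) differed at least 4-fold, 16 of them higher in KO, against a median of 26.7% in 10000 sets matched on expression (95th percentile 40%), but Dcn, which had been seen as a fibroblast marker, is among the 17, and some of these genes lie in the loci of Meg3, Dlk1 and Sgce or share another locus. Leaving out Dcn and those loci, with 1 gene per locus over 15 other loci (25 genes), the mean share was 50.6%, against a matched median of 26.7% and a 95th percentile of 46.7%. The 50.6% is a mean over loci, while the matched values are single draws. Draw by draw, the share was above that of its matched set in 95.2% of 10000 draws. Ndn, Peg3, Snrpn and Peg12 were at 0 counts in all WT libraries and at 22.1, 11.9, 10.9 and 9.20 CPM in KO. They lie on chromosome 7 and need not stand for separate loci. Mkrn3, also on chromosome 7, was counted in WT (2.27 CPM) and was 2.51-fold higher in KO. A hypothesis is that imprinted genes as a class are expressed differently in the WT and KO cells. The design does not separate this from an effect of Nono, and no biological explanation was tested.

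The number of changed genes can be set against other splits of the samples. Only 1 of the 10 splits of the 6 libraries gave as many genes as the real one (12980), and the highest other split gave 0. Every other split mixes the genotypes, so their difference becomes spread within the groups and 0 calls follow. That 0 does not tell how many calls arise by chance. With 3 libraries against 3 the splits are too few for a share under 0.05.

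The second pattern is genes at 0 in all libraries of 1 group and at 5 CPM or more in the other. A difference in depth was argued against by a ratio of mean totals of 1.015, and sex chromosomes alone by a share of 10.2% of these genes on X or Y. In Nono and the Y-linked sum, 0 libraries lay with the other group. A single mislabelled library would carry counts and take genes out of this pattern, so that check does not bear on its cause. KO cultures made of the WT cells plus another cell type were argued against by 28 genes of 5 CPM or more in WT with 0 counts in KO, and loss of Nono alone in otherwise equal cells by 3 Y-linked genes at 0 in WT and at 5 CPM or more in KO. Of the genes at 0 in 1 group, 32% had a nearest tested neighbour at 0 in the same group, such as Pcolce2 with Trpc1. Random draws gave a median of 2.34% (95th percentile 4.69%). Of the 101 genes whose neighbour does not overlap them, 20.8% did (random median 1.98%, 95th percentile 4.95%). The draws took genes from anywhere in the genome, so neighbours regulated together would also give an excess. Loss or silencing of stretches of genes is not told apart from this and stays open. The share of Hox genes that differed does not decide on cells of a different origin or clone. Of 22, 8 (36.4%) differed at least 4-fold, 6 lower and 2 higher in KO. The lower ones were Hoxc5, Hoxc6, Hoxa9, Hoxb9 (153 to 13.6 CPM), Hoxa10 and Hoxb13, and the higher ones Hoxa3 (18.1 to 101 CPM) and Hoxd4. The test did not use the position along the body axis that Hox genes mark, so their order was not tested. The matched median was 22.7% and the 95th percentile 36.4%. The Y-linked sum (0 to 0.0795 CPM in WT, 149.9 to 163.3 CPM in KO) argues against cells that are equal but for Nono. A different origin or clone could give such a difference. How much of the other differences goes with origin stays open, because origin is confounded with genotype here.

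The third pattern is shifts of whole chromosomes. Of 19 autosomes, 14 had a median log2 fold change outside the range of random gene sets of their size and 9 lay over 0.3 from the autosomal median, the farthest being chromosome 19 at -0.574 and chromosome 13 at 0.501, and X was at 0.503. GC content and length of transcripts as the whole cause were argued against, since 7 autosomes were still over 0.3 after a correction for both. A difference in chromosome copy number between the KO and WT cells may produce such shifts. Their sizes were not compared with those a copy change would give, and DNA was not analysed here. Copy number and regulation of many genes per chromosome both stay open.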
